A study of Caenorhabditis elegans with 2 samples.

How the data were processed

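Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole L2 larvae of the nematode Caenorhabditis elegans. The strain carries an integrated transgene with FOS-1, a basic leucine zipper (bZIP) transcription factor of the Fos family, fused to the green fluorescent protein eGFP. The labels give 2 biological replicates of 1 group. There is therefore no comparison between groups, and the design implies a description of the sites together with a comparison of the replicates.

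The deposited files are peak lists on the genome builds ce11 and ce10. A relaxed list was deposited for each replicate, made from that replicate's alignment and a control, and a relaxed list was made from both replicates pooled, per the manifests deposited with them. The lists thresholded by the irreproducible discovery rate (IDR), a measure of agreement in rank between replicates, are those of the whole series. Each call has a signal value set by the authors' peak caller, and this signal is not normalized between lists. Each call also has a −log10 q-value as deposited, and all 7446 calls of the IDR list share the same ceiling of 4.25, so peaks were ranked by signal value. The position of each summit within its peak was likewise taken from the deposited lists. The aligner, the peak caller and their versions are not given in the sources used here. The control library was not analysed here, and the read depth of the libraries is unknown.

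Positions are on ce11 throughout, counted from 1, and the ce10 lists served as an alternative. The ce11 chromosomes were matched by name and length to the WBcel235 assembly, with gene models of Ensembl release 115. The 6 nuclear chromosomes hold 100272607 bases. The 7446 IDR peaks were exactly the 7446 calls of highest signal in the pooled relaxed list. The 20145 pooled relaxed calls that overlapped no IDR peak are called low-ranked calls.

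For replicate agreement, the 7446 calls of highest signal were taken from each replicate, and a call was counted as shared with at least 1 bp in common. The expectation was the share of bases where a randomly placed call of the median width would touch the other list. Signal values were correlated across mutually nearest overlapping calls, with 100000 permutations and 1e-05 as the smallest p that they can give. The promoter window ran from 1000 bp upstream to 250 bp downstream of the start of any protein-coding transcript. Shares of summits were compared with shares of bases by an exact binomial test, made two-sided by doubling the smaller tail. The 7 annotation classes were assigned in a fixed order of priority with Benjamini-Hochberg adjustment. Each autosome was divided by length into 3 equal parts, of which the outer ones are called end parts. All tests were two-sided, intervals are 95% Wilson intervals, and p-values were written no lower than 1e-300.

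Sequence patterns were counted within 50 bp of each summit and in windows of the same width centred 300 bp to both sides. Shares were compared by Fisher's exact test over all windows, which leaves out the pairing of each summit with its own flanks. The AP-1 site TGASTCA (S is C or G), the CRE site TGACGTCA, and as controls the E-box CACGTG, the GATA site WGATAR (W is A or T, R is A or G) and the repeat GAGAGAG were fixed before the data were examined. All 7-mers found in at least 60 windows were ranked by their ratio of centre to flanks. The extended GATA site TGATAAG was taken from that ranking, and the site GACGCAGA spans its overlapping 7-mers GACGCAG (rank 5) and ACGCAGA (rank 10), so their tests describe sequences chosen on these peaks. Peaks were also split into 5 groups by signal, and the 7 patterns were compared between the fifth of highest and the fifth of lowest signal. A gene was assigned a peak when an IDR summit lay in its promoter window. The 26 gene lists were tested by Fisher's exact test over 19973 protein-coding genes, adjusted over the 26 lists. The names atf-5, hsp-16.11, hsp-16.49 and daf-21 of these lists matched no gene symbol and were left out. Counts of peaks within 20 kb of fos-1 and unc-119, both expected in extra copies on the transgene, were compared with the genome-wide density by an exact Poisson test.

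The tests, gene lists, alternatives and named genes were fixed before the data were examined. Named genes are the gene with the transcript start nearest to each of the 20 peaks of highest signal, up to 4 members of each list with the highest promoter peak, fos-1, unc-119, jun-1 and the reported FOS-1 targets. Genes named outside this rule are marked as such. The alternatives were the 3723 peaks of highest signal, each replicate's strongest 7446 calls alone, low-ranked calls or genes with a relaxed call as the background, other windows, overlaps, margins and distances, ce10, and stratification of the gene lists by decile of the distance to the next gene upstream. The other sequence patterns and the classes of short RNA gene were put through the same alternatives only after the data were seen. The surroundings of fos-1 were first tested by windows free of any relaxed call (2.27%), which says nothing of the fos-1 window, as that holds 2. The measures in the closing section were chosen after that value was seen. The ce10 overlap expectation used ce11 chromosome lengths, and the pooled relaxed list on ce10 was not used here.

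The p-values run over peaks or genes, which are neither replicates nor independent of each other, so p-values and intervals cover counting error only. The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The procedures were tested on simulated data. Over random sets of genes with a peak, 3.35% of the gene list tests among 19973 genes had an unadjusted p under 0.05, and a planted list with an odds ratio of 3 was estimated at 2.995. An AP-1 site planted in 10% of 7446 random windows raised the share from 0.846% to 10.9% and ranked 1 among the 7-mers.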

Results

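FOS-1 occupancy was mapped by ChIP-seq of an eGFP fusion in whole L2 larvae of C. elegans, in 2 biological replicates of 1 group. Fos proteins bind DNA as dimers with other bZIP proteins such as Jun, and in the worm fos-1 is known for its part in the invasion of the basement membrane by the anchor cell. The IDR-thresholded list held 7446 peaks on ce11, with a median width of 344 bp and signal values from 33.9 to 702. The relaxed lists held 29339 calls in replicate 1, 28938 in replicate 2 and 28259 in the pooled data. The density of IDR peaks was highest on chromosome X, at 87.8 per Mb, and lowest on chromosome IV, at 64.3 per Mb. The signal values are those of the authors, and the read depth behind them is unknown. Intervals and p-values run over peaks or genes and cover counting error only.

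The replicates placed most of their strong peaks at the same sites. Of the 7446 strongest calls of replicate 1, 5975 or 80.2% (95% interval 79.3 to 81.1) overlapped those of replicate 2, against 4.97% for random placement (exact binomial p = 1e-300). In the other direction the share was 80.5%. The peak upstream of cebp-1, which encodes a bZIP protein of the C/EBP family, was the strongest in both replicates, with signal values of 497.7 and 207.3. Among IDR peaks in the fifth of highest signal, 1489 of 1489 were among the strongest 7446 calls of both replicates, and in the fifth of lowest signal 447 of 1490 were. Across 16458 matched calls, log10 signal had a Pearson's r of 0.803 and a Spearman's rho of 0.786 (permutation p = 1e-05 for both, the smallest the permutations can give). The signal of replicate 1 was 1.92 times that of replicate 2 in the median. These correlations run across peaks, which are not independent replicates. With all relaxed calls the overlap was 61.3% against 18.3% for random placement.

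**Figure D1:**
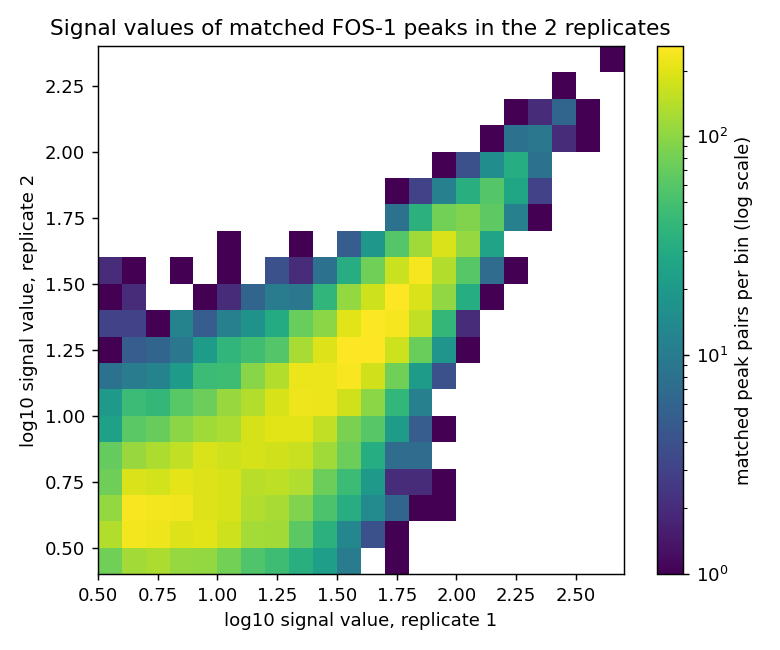
Log10 signal value of 16458 matched calls in replicate 1 (x axis) and replicate 2 (y axis), in bins of 0.1 with the number of pairs as colour on a log scale. The bins spread widely at low signal and narrow towards the highest values, with a Spearman's rho of 0.786.

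FOS-1 summits were more frequent at promoters than the bases there give, and few lay in coding sequence. Of the 7446 summits, 4222 or 56.7% (55.6 to 57.8) fell in the promoter window of a protein-coding gene, which covers 27.1% of bases (exact binomial p = 1e-300, adjusted p = 3.5e-300 over 7 classes). Coding exons held 132 summits or 1.77%, against 18.4% of bases, with the same p. Introns outside promoter windows held 15.04% of summits against 26.8% of bases (exact p = 7.19e-130, adjusted p = 1.68e-129), and 3' UTRs 1.01% against 2.34% (exact p = 2.07e-17, adjusted p = 3.63e-17). Genes of other classes held 2.50% against 3.45% (exact p = 2.97e-06, adjusted p = 4.16e-06), but more than the 2.07% of low-ranked calls. The 5' UTR share outside promoter windows was 0.322% against 0.373% and did not pass the exact test (p = 0.548). Intergenic bases held 22.7% of summits against 21.6% (exact p = 0.0296, adjusted p = 0.0345). That call was lost with the 3723 peaks of highest signal (exact p = 0.0807), with replicate 2 alone (p = 0.0837) and against low-ranked calls (p = 0.858). The median distance from a summit to the nearest transcript start was 564 bp. The promoter share of IDR summits was 1.67 times that of low-ranked calls, of which 33.9% fell in promoter windows. Against low-ranked calls the ratio was 0.161 for coding exons and 0.197 for 3' UTRs, in place of 0.0965 and 0.431 against bases, and with the window of 500 bp upstream the promoter ratio was 3.57 in place of 2.09. The promoter share itself depends on the window, at 42.6% with 500 bp upstream and 71.2% with 2000 bp.

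**Figure D2:**
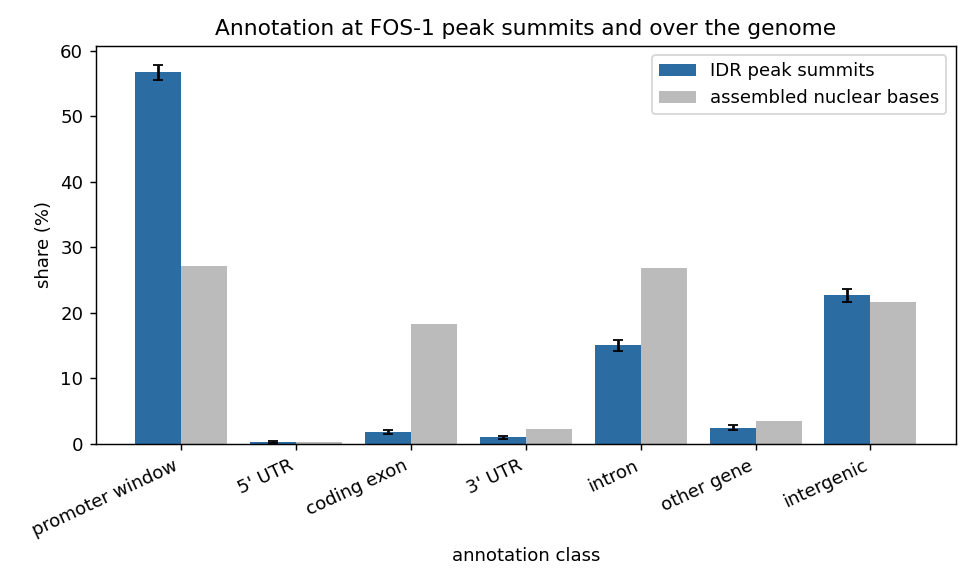
Share of 7446 IDR peak summits (blue, with 95% Wilson intervals) and of assembled nuclear bases (grey) in 7 annotation classes. Promoter windows hold 56.7% of summits and 27.1% of bases, and coding exons 1.77% and 18.4%.

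Chromosome X and the central parts of the autosomes held more FOS-1 summits than their length gives. X held 1555 summits or 20.9% (19.98 to 21.8) against 17.7% of bases (exact binomial p = 1.27e-12, adjusted p = 1.27e-12 over 2 tests). The end parts of the autosomes held 3250 of 5891 autosomal summits or 55.2%, against 66.7% of bases (exact p = 1.08e-74, adjusted p = 2.16e-74). Against low-ranked calls both directions turned, and neither difference passed Fisher's exact test, at 0.957 times their share on X (p = 0.0895) and 1.01 times their share in the end parts (p = 0.366).

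Genes of short structural RNAs were frequent neighbours of FOS-1 summits. Within 250 bp of a tRNA, snoRNA, snRNA or rRNA gene lay 384 summits or 5.16% (4.68 to 5.68), 8.17 times the share of bases (exact binomial p = 1.93e-209). tRNA genes had 248 summits or 3.33% near them, 10.3 times the share of bases (exact p = 5.18e-157, adjusted p = 2.07e-156 over 4 classes). snoRNA genes, whose products guide the modification of ribosomal RNA, had 1.40% of summits at 6.52 times (exact p = 1.91e-48, adjusted p = 3.83e-48). snRNA genes of the splicing machinery had 33 summits at 5.70 times (exact p = 1.18e-14, adjusted p = 1.58e-14). No IDR summit lay next to the 20 rRNA genes, where the share of bases was 0.0188% and the exact test did not pass (p = 0.492). Among the 3723 peaks of highest signal, the share next to tRNA genes was lower, at 2.02% or 6.21 times the share of bases, and that next to snoRNA genes higher, at 2.07% or 9.66 times. The ratio for all short RNA genes was 3.40 within 1000 bp, and against low-ranked calls it was 3.28, with 3.02 for tRNA, 3.80 for snoRNA and 4.25 for snRNA genes.

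The AP-1 site, the sequence that Fos and Jun dimers bind, was found at a small part of the peaks, and GATA sites at 52.9% of them. TGASTCA lay within 50 bp of 264 summits or 3.55% (3.15 to 3.99), against 1.05% of flanking windows, a ratio of 3.36 (Fisher's exact p = 2.1e-35, adjusted p = 2.94e-35 over 7 patterns). It was more frequent at strong peaks, at 6.25% of the fifth of highest signal and 2.68% of the fifth of lowest signal (Fisher's exact p = 2.09e-06, adjusted p = 4.89e-06 over 7 patterns). The GATA site WGATAR, which GATA factors such as ELT-2 of the intestine bind, lay at 3939 summits (51.8 to 54.03%) against 20.7% of flanks, a ratio of 2.55 (exact p = 1e-300, adjusted p = 3.5e-300). The GAGA repeat lay at 9.83% against 1.42% (exact p = 6.81e-179, adjusted p = 1.59e-178) and the E-box at 3.98% against 1.65% (exact p = 5.26e-25, adjusted p = 6.13e-25). The CRE site lay at 0.819% against 0.557% (exact p = 0.0262, adjusted p = 0.0262). The CRE call was lost at summits outside promoters (exact p = 0.575), with the 3723 peaks of highest signal (p = 0.471) and against low-ranked calls (p = 0.588). It was also lost within 100 bp with flanks at 500 bp (exact p = 0.0809), where the width and the flanks changed together. The share at IDR summits over that at low-ranked calls was 1.68 for the AP-1 site, 1.92 for the GATA site, 1.93 for the E-box and 2.32 for the GAGA repeat.

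Among 7796 7-mers ranked by their ratio of centre to flanks, TGACTCA, which is an AP-1 site, had rank 206. Rank 1 was CTTATCA with its reverse complement TGATAAG, the extended GATA site. It lay at 1699 summits or 22.8% (21.9 to 23.8) against 1.74% of flanks, a ratio of 13.1. GACGCAGA lay at 397 summits or 5.33% against 0.463%, a ratio of 11.5. With windows of 100 bp and flanks at 500 bp the ratios were 7.03 and 8.21, and against low-ranked calls 4.45 and 2.90. Both sites were chosen from the ranking on these peaks, where GACGCAGA spans the 7-mers of ranks 5 and 10, so their excess is not independent evidence. The extended GATA site was also more frequent at strong peaks, with 28.5% in the fifth of highest signal and 15.8% in the fifth of lowest signal (Fisher's exact p = 5.12e-17, adjusted p = 3.58e-16). The GATA site rose from 46.6 to 57.4% (exact p = 4.3e-09, adjusted p = 1.5e-08) and GACGCAGA from 4.43 to 7.05% (exact p = 0.00211, adjusted p = 0.00369).

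**Figure D3:**
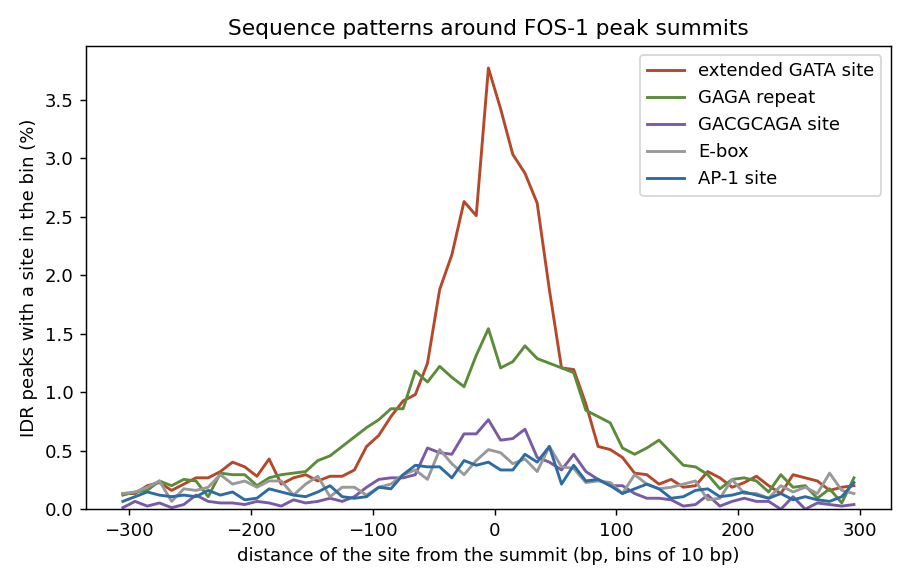
Share of 7446 IDR peaks with a site in each 10 bp bin (y axis, percent) by distance from the summit (x axis, bp) for the extended GATA site, the GAGA repeat, GACGCAGA, the E-box and the AP-1 site. Of these 5, the extended GATA site, chosen on these peaks, stands highest at the summit, at 3.77% in the bin just before it against 0.403% for the AP-1 site.

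Peaks at cebp-1, cdc-48.1, jun-1 and vhp-1 were among the 7 of highest signal. Of the 20 peaks of highest signal, 16 were in promoter windows, 2 in introns and 2 intergenic, 10 had a GATA site and 2 an AP-1 site. The strongest, with a signal of 702, covered chromosome X from 1454407 to 1454846, in the promoter window of cebp-1. The peak of rank 2, with a signal of 485, lay on chromosome II from 10563438 to 10563701, nearest to the start of cdc-48.1, which encodes an AAA ATPase that acts with the proteasome. The peak of rank 4, with a signal of 436.5 and an AP-1 site, covered a start of jun-1, the worm Jun gene, on chromosome II from 9112899 to 9113294. Rank 6, also with an AP-1 site, was the peak at rib-2, which encodes a glycosyltransferase of heparan sulfate synthesis. Rank 7, with a signal of 426, lay in an intron of vhp-1, the gene of a MAP kinase phosphatase, on chromosome II from 5336858 to 5337266. Promoter peaks of the ribosomal protein genes rpl-3 (signal 419) and rpl-15 (signal 353.5) had ranks 9 and 15.

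Promoter peaks were assigned to 4681 of 19973 protein-coding genes or 23.4%, and 12 of the 26 gene lists differed from the remaining genes. Of 76 cytosolic ribosomal protein genes, 67 or 88.2% (79.0 to 93.6) had a promoter peak, with an odds ratio of 24.7 (Fisher's exact p = 5.83e-33, adjusted p = 7.57e-32). Among bZIP genes, 20 of 26 or 76.9% had a promoter peak (odds ratio 10.9, exact p = 1.24e-08, adjusted p = 1.07e-07). They included cebp-1, jun-1, xbp-1 of the unfolded protein response (signal 260.3) and zip-2 of the response to pathogens (signal 237.7). The V-ATPase, the proton pump of acidic organelles, had 14 of 20 genes with a promoter peak (odds ratio 7.64, exact p = 1.32e-05, adjusted p = 5.73e-05), with vha-1 at a signal of 257.5. Nuclear hormone receptors had 97 of 269, or 36.1% (odds ratio 1.86, exact p = 2.92e-06, adjusted p = 1.9e-05), with nhr-8 the strongest at 276.3. With only genes that had a relaxed pooled call as the background, these 4 lists still passed (exact adjusted p = 2.33e-11, 1.8e-04, 0.0258 and 0.0258 in that order). The odds ratio was then 8.38 for ribosomal protein and 19.8 for bZIP genes, and with the 3723 peaks of highest signal it was 11.5 for ribosomal protein genes.

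Shares above the remaining genes were also found for 4 other lists. MAP kinase signalling had 12 of 21 genes (odds ratio 4.36, exact p = 9.1e-04, adjusted p = 0.00263). Its members kgb-1, which encodes a kinase of the JNK family, and pmk-3, which encodes a p38 kinase, had promoter peaks of signal 177.5 and 177.1, both with an AP-1 site. The proteasome had 18 of 33 genes (odds ratio 3.93, exact p = 1.11e-04, adjusted p = 4.11e-04), with rpn-3 at 215.3. Intestine markers had 12 of 22 (odds ratio 3.93, exact p = 0.00158, adjusted p = 0.0041), among them the GATA factor gene elt-2 (signal 166.6) and the peptide transporter gene pept-1 (signal 142.3). Actin and adhesion genes had 14 of 29 (odds ratio 3.06, exact p = 0.00342, adjusted p = 0.00808), led by unc-112, a kindlin gene, at 280.3. With only genes that had a relaxed pooled call as the background, the calls of these 4 lists were lost. The odds ratio was 2.37 for MAP kinase signalling (exact adjusted p = 0.287), 1.78 for the proteasome (p = 0.343) and 1.26 for actin and adhesion (p = 0.815), while that of intestine markers stayed at 3.96, with 15 genes left (p = 0.121). The proteasome call was also lost with the 3723 peaks of highest signal (exact adjusted p = 0.141), and the actin and adhesion call with the window of 500 bp upstream (adjusted p = 0.0571).

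Chemoreceptor, cuticle collagen, major sperm protein and germline genes had few promoter peaks. Chemoreceptor genes had 48 of 1353, or 3.55% (2.69 to 4.67), with an odds ratio of 0.111 (exact p = 9.32e-98, adjusted p = 2.42e-96). The strongest of the 48 was at srz-62, with a signal of 419.2. Cuticle collagens had 17 of 176, or 9.66% (odds ratio 0.347, exact p = 3.87e-06, adjusted p = 2.01e-05), with col-63 at 138.5. Major sperm protein genes had 0 of 31, with a Wilson upper bound of 11.03% (exact p = 4.09e-04, adjusted p = 0.00133). Germline genes had 0 of 23, with an upper bound of 14.3% (exact p = 0.00474, adjusted p = 0.0103). With only genes that had a relaxed pooled call as the background, collagens still passed (exact adjusted p = 1.44e-06) and the others did not (adjusted p = 0.117 with an odds ratio of 0.655 for chemoreceptors, 0.428 for 2 major sperm protein genes and 0.287 for 3 germline genes). With the 3723 peaks of highest signal the counts were still 0 of 31 and 0 of 23, but the share of other genes was 12.59%, and the major sperm protein and germline calls were lost (exact adjusted p = 0.0707 and 0.211), and the germline call with the window of 500 bp upstream (adjusted p = 0.0567).

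**Figure D4:**
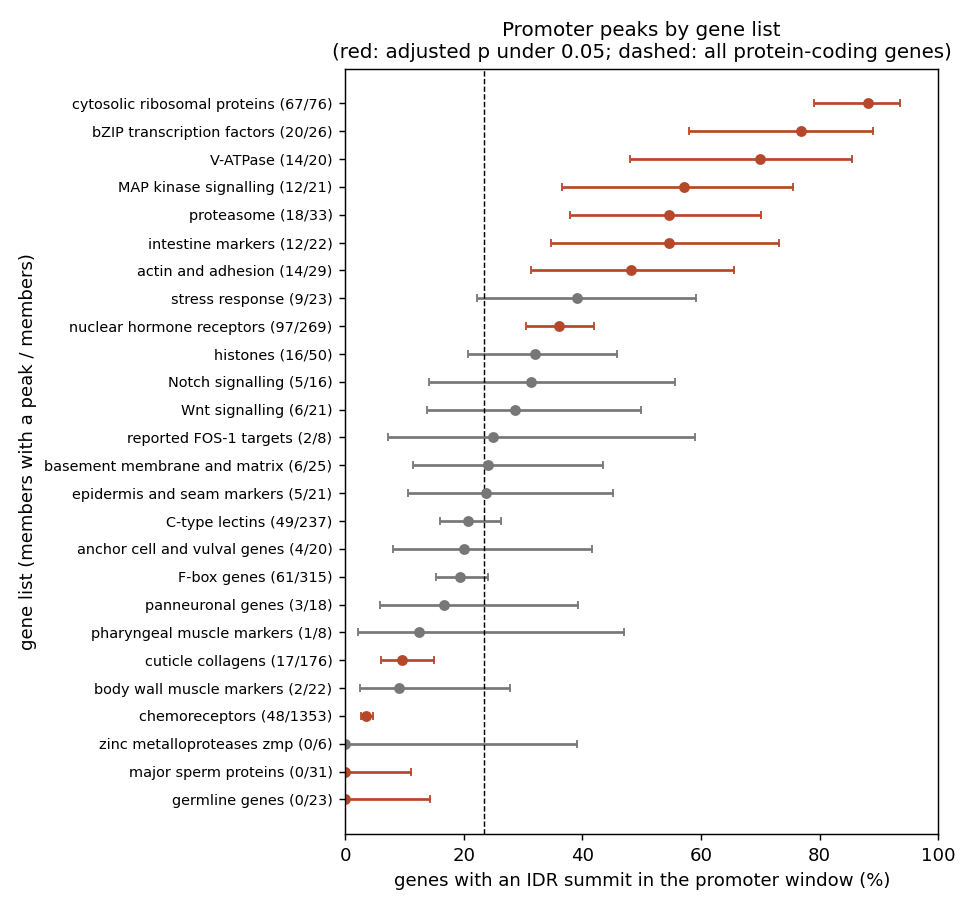
Percent of the members of each of 26 gene lists with an IDR summit in the promoter window (x axis, points with 95% Wilson intervals), red where the adjusted p is under 0.05, with the share of all protein-coding genes (23.4%) as a dashed line. Cytosolic ribosomal proteins stand highest at 88.2%, and major sperm protein, germline and zmp genes have none.

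The lists of reported FOS-1 targets, anchor cell and vulval genes, basement membrane and matrix genes and zmp genes did not pass the test. Of 8 genes reported to depend on fos-1, 2 had a promoter peak (Fisher's exact, adjusted p = 1). These were egl-13, a SOX factor gene with a peak of signal 86.2 and rank 2308 on chromosome X, and mig-10, a gene of cytoskeletal guidance with a peak of signal 73.8 and rank 3046 on chromosome III. Both peaks lay inside the gene, upstream of an internal transcript start. The summits were at 5671011 in egl-13 (5663837 to 5674067) and at 8299934 in mig-10 (8279101 to 8305837). The other genes, cdh-3, egl-43, him-4, itr-1, plc-1 and zmp-1, had none. Anchor cell and vulval genes had 4 of 20, with egl-17 at 95.4 and let-23 at 51.9, and basement membrane and matrix genes had 6 of 25, with lon-2 at 112.6 (exact adjusted p = 1 for both). None of the 6 zmp metalloprotease genes had a promoter peak (Fisher's exact p = 0.347, adjusted p = 0.512). Lists of this size leave wide intervals, such as 7.15 to 59.1% for the 8 genes. The chromatin came from whole L2 larvae. A missing peak therefore does not show that FOS-1 is absent from a promoter in the anchor cell, in another single tissue or at another stage.

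The remaining lists did not pass the test. Stress response genes had 9 of 23 with hsp-3 at 173.3 (exact adjusted p = 0.171), and histones 16 of 50 with his-37 at 305.9 (exact adjusted p = 0.291). Notch signalling had 5 of 16 with sel-10 at 94.8 (exact adjusted p = 0.757), and Wnt signalling 6 of 21 with pry-1 at 125.1 (adjusted p = 0.788). F-box genes had 61 of 315 (exact adjusted p = 0.174) and C-type lectins 49 of 237 with clec-78 at 306.6 (adjusted p = 0.512). Epidermis and seam markers had 5 of 21, panneuronal genes 3 of 18, body wall muscle markers 2 of 22 (1 of 22 with replicate 2 alone, adjusted p = 0.0823 by the exact test) and pharyngeal muscle markers 1 of 8, which was pha-4 (exact adjusted p = 1, 0.922, 0.233 and 0.854). With the window of 2000 bp upstream, 3 lists newly passed, with Wnt signalling higher (exact adjusted p = 0.0499), and F-box genes (p = 0.00987) and C-type lectins (p = 0.0484) lower.

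No IDR peak lay within 20 kb of fos-1, on chromosome V from 6003601 to 6016087, or of unc-119, on chromosome III from 10902641 to 10908935. At fos-1, 3.90 peaks were expected from the genome-wide density (exact Poisson p = 0.0406). If peaks were evenly spread, a count of 0 would have a one-sided upper bound of 3 counts, or 0.770 times that density. At unc-119, 3.44 were expected (exact p = 0.0643), and the strongest 7446 calls of either replicate alone held 1 there (exact p = 0.285). At jun-1, on chromosome II from 9113157 to 9132231, a locus tested after its values were seen, 15 peaks lay within 20 kb against 4.39 expected (exact p = 1.12e-04). The Poisson test takes peaks as evenly spread, whereas 8.72% of windows of the fos-1 length centred on protein-coding genes held no IDR peak. The fos-1 call was lost within 50 kb (3 peaks against 8.35 expected, exact p = 0.0666) and with the 3723 peaks of highest signal (p = 0.285), and unc-119 passed within 50 kb (0 against 7.89, p = 7.47e-04).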

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

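The tests of sites at low-ranked calls, of GATA sites, of AP-1 sites at summits without a GATA site, of the surroundings of fos-1 and unc-119, of tRNA genes with a sequence of their own against the genome-wide density, and of the strongest peaks beside tRNA genes were chosen only after the result was seen.

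Calls outside the IDR list drew attention because they carried a signal although no comparison rests on them alone. Of 20145 low-ranked calls, 426 or 2.11% had an AP-1 site against 0.891% of flanks (Fisher's exact p = 1.15e-33), and 1034 or 5.13% had the extended GATA site against 1.42% (exact p = 1.26e-145).

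GATA sites were more frequent than AP-1 sites at IDR summits. They were also more frequent in flanks, at 20.7% against 1.05%, which leaves less room for a high ratio. Which site had the higher ratio to its flanks depended on the window and the measure. The shorter GATA pattern had the lower ratio of shares within 50 bp (2.55 against 3.36) and within 100 bp with flanks at 500 bp (1.76 against 2.97). It had the higher ratio within 25 bp (3.27 against 2.69), and the higher odds ratio within 50 bp (4.29 against 3.45). Sequence of protein-coding promoter windows alone is argued against by a GATA ratio of 2.78 at summits outside them, not below the 2.38 inside them. That comparison replaced an earlier bound, written for the extended GATA site, after the values were seen. Windows of all gene classes held 69.5% of IDR summits, so some summits counted as outside lay near starts of other transcripts. A property of called regions in general stays open only in part. The GATA share at IDR summits was 1.92 times that at low-ranked calls, against 1.68 times for the AP-1 site. Over flanks, the GATA ratio was 2.55 at IDR summits and 1.36 at low-ranked calls, against 3.36 and 2.37 for the AP-1 site. These ratios argue against a GATA excess of the same size at all called regions. An excess that differs with rank stays open, since the E-box (2.42 and 1.28) and the GAGA repeat (6.94 and 2.83) also had lower ratios at low-ranked calls. A library of another factor cannot be told apart from FOS-1 binding either: at summits without a GATA site the AP-1 ratio was 3.42, between those of the E-box (2.53) and the GAGA repeat (8.42), and from the fifth of lowest to that of highest signal the shares of the AP-1 site (2.33 times), the extended GATA site (1.81 times), GACGCAGA (1.59 times) and the GATA site (1.23 times, adjusted p = 1.5e-08 by Fisher's exact test) all rose, while those of the E-box (0.699 times) and the GAGA repeat (1.16 times) did not pass the test. No biological explanation was tested, as the design has 1 group.

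No IDR peak lay within 20 kb of fos-1, and an ordinary gap cannot be told apart from a local lack of calls, since the measures fall on both sides of 5%. Of windows of the same length centred on protein-coding genes, 8.72% held no IDR peak and 7.05% held 2 relaxed pooled calls or fewer, the number at fos-1. Gaps as long as the one over fos-1 cover 4.83% of the genome in the pooled list, 4.56% in replicate 1 and 1.52% in replicate 2, and relaxed calls within 20 kb of fos-1 were at 0.135 times the genome-wide density in the pooled list, 0.130 times in replicate 1 and 0.264 times in replicate 2 (exact Poisson p = 9.43e-05, 5.75e-05 and 0.00153, too small where calls are unevenly spread). Extra copies of these loci in the control could also lower calls, and relaxed calls around unc-119 were at 0.153 times the genome-wide density in the pooled list and 0.148 times in replicate 1, but 0.524 times in replicate 2 (exact Poisson p = 0.0894), 8.92% of windows of that length held as few as the pooled list, and the control was not analysed here. No biological explanation was tested.

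IDR summits were frequent next to tRNA genes. Weak peaks are not the whole source, as the share among the 3723 peaks of highest signal was still 6.21 times that of bases (exact binomial p = 4.71e-34), although these held only 75 of the 248 summits and their share was 1.83 times that of low-ranked calls. Reads shared between identical copies may add to it, since 232 of 469 tRNA genes with an identical copy had an IDR summit, 1.91 times the share among those with a sequence of their own (exact p = 4.78e-07). Of 143 tRNA genes with a sequence of their own, 37 had an IDR summit, 6.03 times the share at the genome-wide density. That value does not exclude shared reads at these genes, as near-identical copies were not looked for. Whether a second kind of site is present cannot be told. The GATA site was 0.381 times as frequent beside tRNA genes as at other summits. Neither share was set against flanks, so a difference in the surrounding sequence is not excluded. Whether these summits depend on FOS-1 was not tested, as the control was not analysed here. No biological explanation was tested.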

How the results depend on the processing

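The alternatives for patterns other than the AP-1 site, for the separate classes of short RNA gene, for AP-1 sites against low-ranked calls, at summits at least 200 bp apart and at summits without a GATA site, and the windows centred on genes were chosen only after the data were seen. Of the values recomputed for the main results, 103 kept their direction and their side of the threshold or stayed within the set limits, 4 reversed, 5 were weaker, 1 was stronger and 2 moved. For what follows the cause was not tested unless stated. Against low-ranked calls, the ratio of shares was 1.21 for genes of other classes (exact p = 0.0329), 0.957 for X and 1.01 for the end parts of the autosomes, all reversed, and 1.005 for intergenic summits. With the 3723 peaks of highest signal, the intergenic share was 22.8%, fos-1 still had 0 peaks but against 1.95 expected, and 2511 genes had a promoter peak, since fewer peaks were used. Within 50 kb, fos-1 had 3 peaks and unc-119 0. With only genes that had a relaxed pooled call as the background, 5 lists passed, out of fewer genes.

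The lists whose odds ratio reversed passed the test in neither setting. With the 3723 peaks of highest signal the odds ratio was 0.604 for basement membrane, 0.994 for Notch signalling, 0.948 for histones and 0.732 for epidermis. With the window of 500 bp it was 0.775 for epidermis, and with that of 2000 bp 0.804 for FOS-1 targets, 0.938 for basement membrane, 0.964 for epidermis and 1.21 for panneuronal genes. Against genes with a relaxed call it was 0.494 for FOS-1 targets, 0.846 for basement membrane, 0.658 for Wnt signalling, 0.823 for Notch signalling and for epidermis, 1.41 for F-box genes and 1.28 for lectins.

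With each replicate alone, the 5' UTR share ranged from 0.322 to 0.390%, crossing the 0.373% of bases, and the intergenic share from 22.4 to 22.8%. The odds ratio ranged from 0.855 to 1.42 for anchor cell genes, 0.855 to 1.28 for basement membrane, 0.804 to 1.03 for epidermis and 0.660 to 1.32 for panneuronal genes, and was 0.163 for body wall muscle without replicate 1 in place of 0.326. The promoter share ranged from 55.3 to 56.3%, the AP-1 share from 3.44 to 3.55%, the GATA share from 48.5 to 53.1% and the share next to short RNA genes from 5.05 to 5.45%, and 12 lists passed each time. Replicate overlap and correlation need both replicates and have no such value. A pair of ratios gave no value, as rRNA genes had 0 summits in both sets and no odds ratio could be formed for pharyngeal markers with 1 of 1 gene. Depth limits could not be assessed, as the lists hold no read counts. No paired analysis was possible because the design has 1 group.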

Other observations

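The tests below were chosen only after the data were seen.

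Genes with promoter peaks differed in the sequence under the strongest promoter summit, in 72 tests of 18 lists and 4 patterns with Benjamini-Hochberg adjustment. The GATA site lay at 3 of 67 ribosomal protein genes or 4.48%, against 46.2% of other genes with a promoter peak (Fisher's exact, adjusted p = 5.3e-12), and the extended GATA site at 0 of 67 (adjusted p = 9.82e-06). Proteasome genes had the GATA site at 2 of 18 (exact adjusted p = 0.0295). Intestine markers had it at 11 of 12 (exact adjusted p = 0.0194), C-type lectins, a family with many members in intestine and immunity, at 42 of 49 (adjusted p = 2.44e-07), and F-box genes at 44 of 61 (adjusted p = 5.93e-04). The AP-1 site passed the adjusted test in none of the 18 lists. Its highest share was at actin and adhesion genes, 3 of 14 (exact adjusted p = 0.0807), 2 of them unc-112 and act-2.

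Some genes held many separate IDR summits. Counted over the gene and 5 kb to both sides, vhp-1 had 14 summits in 27.6 kb, jun-1 13 in 29.1 kb, pkg-2 13 in 27.3 kb, lin-14 13 in 30.3 kb and daf-16 11 in 36.2 kb. The genes pkg-2, lin-14 and daf-16 were singled out after their values were seen.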
